A study of Arabidopsis thaliana with 8 samples.

How the data were processed

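The values analysed are those of the deposited table of 3439 spots on 8 arrays, 4 of WT and 4 of the tatA antisense line, 1 column per array. Per the labels, the RNA was total RNA of ecotype Columbia 0, and groups and replicate numbers were taken from the sample titles. The deposited values are spot intensity on a linear scale, never negative, listed at 0 on 172 to 248 spots per array and ending at an upper limit of 100. How the authors read the spots, subtracted background, scaled or filtered them is not given in the sources used here. The scaling of each array therefore stays unknown. The deposited intensity had medians of 0.429, 0.430, 0.531 and 0.524 for WT replicates 1 to 4, and of 0.372, 0.365, 0.390 and 0.368 for tatA replicates 1 to 4. Each column holds 1 sample and 1 colour, so direction is that of the groups: changes are tatA relative to WT.

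A value of 0 was read as a spot with no signal above its background, so that folds of dim genes depend on how zeros are treated. Of the 3439 spots, 64 were at 0 on all 8 arrays, and every tatA array had more spots at 0 than every WT array. Spots at 0 on more than 4 of the 8 arrays, 177 in all, were left out. Remaining zeros, on 240 kept spots, were set to the smallest positive value of their array, and log2 was taken. Spots at the limit, 3 on all arrays and 6 on at least 1, were kept, and their changes are understated. The columns' median log2 values differed by more than 0.1, so quantile normalization between arrays was applied, as set in advance. This makes all arrays share 1 distribution and removes any overall difference in level between the groups. No background correction was added, since the table holds no background values and many values lie at exactly 0.

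Gene names come from the platform annotation of the array in GEO, which gives 1 gene for 692 spots, several genes for 870 and none for 1877. Spots with several genes were not named. Through the gene identifier, 690 of the 692 matched a locus in the RefSeq annotation of the TAIR10.1 assembly, for 689 loci. That annotation was used for names only, and no coordinates are given because no build is named for the array. The gene measured by 2 spots, AT2G25870, was averaged, although its spots disagreed (log2 changes of -0.37 and 1.61). This left 3261 rows, 646 of them with a locus. TATA, TATB and TATC were not among the spots named here, so the comparison of the targeted transcript, with its alternatives, was not run.

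The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with group as the only term. A Benjamini-Hochberg adjusted p under 0.05 over the 3261 rows was the threshold. Gene lists were 22 sets with 375 genes, written before the data were examined, and those with at least 3 tested members were tested with camera at a preset correlation of 0.01. Values in the text are mean intensities on the deposited scale ± SD over 4 arrays, and log2 changes with their SE after normalization. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

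The genes named were set by a rule: TATA and the other translocase subunits; the 12 largest rises and 12 largest falls that passed and whose groups did not overlap; up to 3 members per list by smallest p, or all that passed where these were 4 or fewer; and at most 2 unnamed spots per direction. Because most rows carry no name, the 12 per direction were taken among rows with a gene name. That reading was chosen after the annotation was seen. AT1G64510, the remaining tested member of the ribosomal list, was named after its value was seen.

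Alternatives fixed before the data were examined were the deposited scale, median centring, scaling to the 75th percentile, leaving out the dimmest 25% or 50% of genes, and an offset of 0.118 (the 10th percentile of positive values) before log2. Others were no intensity trend, robust variance, array weights, the replicate number as a fixed or random block, leaving out each array, an estimated inter-gene correlation, and fry. Those added after seeing the data were the replicate pairs 1-2 and 3-4 as a random block or averaged, averaged with the pair number as a fixed block, the pair number as a fixed block on all arrays, and each pair alone. Also added were spots with any 0 left out, and centring on neighbouring spot numbers, alone and with the pairs as a random block.

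Whether replicate numbers pair the samples was checked before the fits were compared. Deviations from the group means of same-numbered WT and tatA arrays correlated across genes at 0.284, 0.311, 0.266 and 0.337 for replicates 1 to 4. All lie over 0.1, the limit set for taking the number into account, so it was used as a block in alternative fits. The main fit kept group as its only term. A shift common to replicates 1-2 or 3-4 of both groups also raises these correlations. Arrays with unlike numbers were not set beside them, so they cannot show that a number pairs 2 samples. No label says what a number marks. Values with the replicate number as a block are given beside a result where they change its call. A closer likeness was found between replicates 1 and 2, and between 3 and 4, within each group, with a consensus correlation of 0.546 within such pairs.

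The test was checked on simulated data for the 3261 rows with 200 changed genes. With independent arrays it recovered 48.5% of changes of 1 on the log2 scale, with 5 false calls among 102, and 76.5% of changes of 2, with 5 among 158. With the correlation of 0.546 within pairs, 48 of 163 calls were false at a change of 1 and 70 of 238 at a change of 2. With the pairs as a random block these were 7 of 86 and 8 of 159. With pairs averaged there were 0 calls at a change of 1, and 1 of 103 was false at a change of 2. For this reason the counts with the pairs as a block, and averaged, stand beside the main count in the text. The simulated genes were independent, with normal errors, the same pair correlation for all and no shift common to both groups. The random block assumes such data, so its low rate of false calls there need not hold for the measured values. The share of genes whose groups do not overlap by chance was simulated for 100000 unchanged genes, without and with the correlation of 0.546 within pairs.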

Results

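Transcript levels were measured on 8 single-colour arrays of Arabidopsis thaliana (ecotype Columbia 0). Total RNA of 4 wild-type samples (WT) was compared with that of 4 samples of an antisense line of tatA. TatA is a subunit of the twin-arginine translocation (TAT) pathway, which carries folded proteins across the thylakoid membrane of the chloroplast on the energy of the ion gradient. The tissue is not given in the labels. Each array held 3439 spots, of which 3261 genes or unnamed spots were tested. Only 646 of these carried the name of a single gene, and the other 2615 are known here by spot number alone. Median spot intensity ran from 0.429 to 0.531 on the WT arrays and from 0.365 to 0.390 on the tatA arrays. The number of arrays, 4 per group, limits the precision of every value. Transcripts of TATA and of the other subunits of the translocase, TATB and TATC, are not analysed here, so no value of the targeted gene stands beside the comparison.

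The question of the study was how the transcript profile of the tatA line differed from that of WT. In the tatA line, transcripts of a photosystem I assembly factor (AT1G22700), of a photosystem II subunit (PSBW) and of dihydroxyacid dehydratase (AT3G23940) were higher than in WT. Transcripts of a CRM-domain RNA-binding protein (AT4G29750), of the thylakoid Sec translocase subunit SECE1 and of the circadian-regulated gene CCL were lower. With replicates 1-2 and replicates 3-4 of each group averaged, PSBW, SECE1 and CCL did not pass (limma adjusted p = 0.0537, 0.224 and 0.0729). In all, 1046 of 3261 genes or spots passed at a Benjamini-Hochberg adjusted p under 0.05 (limma), 499 of them higher and 547 lower in tatA. Among those with a gene name 203 passed, 105 higher and 98 lower. Changes of more than 1 on the log2 scale after quantile normalization were more often rises, with 296 against 187 falls. For 974 of the 1046, the 4 tatA values lay on 1 side of the 4 WT values. This was so for 35.5% of all genes tested. Chance gives 2.86% for independent arrays, and 9.0% in simulated unchanged genes with the correlation of 0.546 found between paired replicates, described next.

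These counts depend on what is taken as a replicate. Within each group, replicates 1 and 2 resembled each other, as did replicates 3 and 4, and with these pairs as a random block 537 genes passed, 291 higher and 246 lower. With each pair averaged to 1 value, which leaves 2 values per group, 57 passed, 41 higher and 16 lower. The split between rises and falls also depends on the scaling. On the deposited scale, without normalization between arrays, 1390 passed, 310 higher and 1080 lower, and the median gene lay at -0.47 on the log2 scale in tatA against WT. Changes below are given after quantile normalization, relative to the array as a whole.

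**Figure D1:**
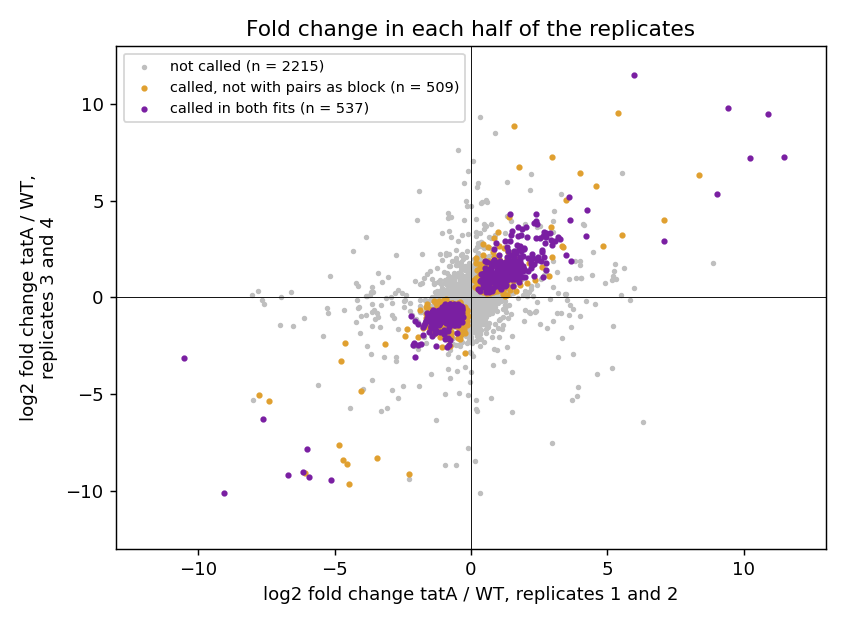
Log2 fold change of tatA over WT for 3261 genes or spots, from replicates 1 and 2 (x axis) and from replicates 3 and 4 (y axis). Grey points did not pass in the fit of all 8 arrays, orange points (509) passed there but not with the replicate pairs as a random block, and purple points (537) passed in both. All 1046 that passed had the same sign in both pairs of replicates. They were selected by a fit of these same arrays, which favours such genes, so this is not replication. Of genes that passed in each pair of replicates alone, 609 had the same sign and 23 the opposite sign. Across all genes, which are not independent replicates, Spearman's rho was 0.545.

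Of the 12 largest rises among named genes, 9 could be expressed as a fold, and 8 of the 12 passed with the replicate pairs as a random block. AT1G22700, a tetratricopeptide protein needed to assemble photosystem I (PYG7), went from an intensity of 0.0866 ± 0.0150 in WT to 0.864 ± 0.118 in tatA (SD, n = 4 arrays), a log2 change of 3.81 (SE 0.23, limma adjusted p = 1.55e-05). AT3G23940, dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose by 3.13 (SE 0.29, adjusted p = 0.000124). AT2G30100 rose by 2.90 (SE 0.19, adjusted p = 2.59e-05), from 0.318 ± 0.0572 to 1.88 ± 0.137 (SD, n = 4 arrays). These 3 rises also passed with each replicate pair averaged (adjusted p = 0.0302, 0.0420 and 0.0339). The size of rises from a low WT level depends on the offset before log2: with an offset of 0.118, AT1G22700 rose by 2.53 and AT3G23940 by 1.93.

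FBL17, an F-box protein that drives germ cell division in pollen, rose by 3.16 (SE 0.34, adjusted p = 0.000273). AT5G22620, a member of the phosphoglycerate mutase family, rose by 3.04. AT5G46390, a member of the C-terminal processing peptidase family, also rose by 3.04. With the offset these 3 rises were 1.73, 1.99 and 2.099. AT4G35660 rose by 2.71, from 1.57 ± 1.09 to 7.21 ± 1.38 (SD, n = 4 arrays), with 1.86 in replicates 1-2 and 3.57 in replicates 3-4. AT4G14330, a kinesin-related protein of the phragmoplast (PAKRP2), rose by 4.27 (SE 1.25) and AT4G05490 by 2.77 (SE 0.79), but neither passed with the replicate pairs as a random block (adjusted p = 0.0578 and 0.106). Their size is poorly fixed: AT4G14330 rose by 1.76 in replicates 1-2 and 6.77 in replicates 3-4, and AT4G05490 by 1.38 and 4.16. With the offset their values were 1.57 and 1.24, and leaving out 1 array moved AT4G14330 between 3.51 and 5.48 and AT4G05490 between 1.98 and 3.35.

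In the other 3 of the 12 largest named rises, WT arrays were listed at 0, so that no fold is given. AT3G25680 was at 0 on 2 WT arrays, with a WT mean of 0.0107, and had a tatA mean of 0.504. AT4G31930 was at 0 on 3 WT arrays, with means of 0.0141 in WT and 0.163 in tatA. AT2G22050 was at 0 on 1 WT array, with means of 0.0209 in WT and 0.0932 in tatA. Adjusted p was 0.0022, 0.0146 and 0.0426 for these genes, and 0.0166, 0.114 and 0.154 with the replicate pairs as a random block. These p-values rest in part on the value set for zeros, but the 3 calls of the main fit were kept with the offset. Leaving out 1 array at a time, AT2G22050 no longer passed in 7 of 8 fits (adjusted p from 0.0118 to 0.118), AT4G14330 in 6 (0.00941 to 0.0758) and AT4G05490 in 3 (0.0161 to 0.0708).

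Among named genes that passed, AT4G31530, which encodes a protein with an NAD(P)-binding fold, had the largest fall after quantile normalization. On the deposited scale and with median or 75th percentile scaling it fell less than AT4G29750 (-2.21 against -2.44 on the deposited scale). The intensity of AT4G31530 went from 32.6 ± 4.44 in WT to 7.03 ± 0.759 in tatA (SD, n = 4 arrays), a log2 change of -2.58 (SE 0.27, limma adjusted p = 0.000226), and of -1.86 with median centring and -1.81 with 75th percentile scaling. Quantile normalization gave AT4G31530 the same log2 value on WT replicates 1 and 2 (4.86), and the same on WT replicates 3 and 4 (5.96). Its SE therefore does not measure the spread in intensity within these WT pairs. AT4G29750, which carries the CRM domain found in splicing factors of organelle introns, had a log2 change of -2.29 (SE 0.11, adjusted p = 6.62e-06), with means of 8.73 ± 0.964 and 1.61 ± 0.147 (SD, n = 4 arrays). AT1G13990 changed by -1.52 (SE 0.11, adjusted p = 3.27e-05). These 3 falls also passed with each replicate pair averaged (adjusted p = 0.0481, 0.0302 and 0.0339).

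AT4G39690, which encodes the mitochondrial inner membrane protein MIC60, changed by -1.52 (SE 0.15, adjusted p = 0.000176). CSLA01, of the mannan synthase family, changed by -1.62. CCL, whose transcript stability is under the control of the circadian clock, changed by -1.33, and AT2G11270 by -1.35. AT4G12740, a homologue of the DNA repair glycosylase MutY, changed by -1.71 (-0.86 in replicates 1-2 and -2.55 in replicates 3-4), and AT4G31210, a type IA DNA topoisomerase, by -1.48 (-0.86 and -2.11 in the same pairs). AT2G26110 changed by -1.70, AT2G06040 by -1.43 and AT2G38950, a jumonji-domain protein, by -1.38. With the replicate pairs as a random block, 10 of the 12 falls passed, and AT2G06040 (adjusted p = 0.0612) and AT2G38950 (0.114) did not. Leaving out 1 array at a time, AT2G06040 no longer passed in 5 of 8 fits (adjusted p from 0.0146 to 0.0828), and AT2G26110 only without tatA replicate 3 (0.0536).

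**Figure D2:**
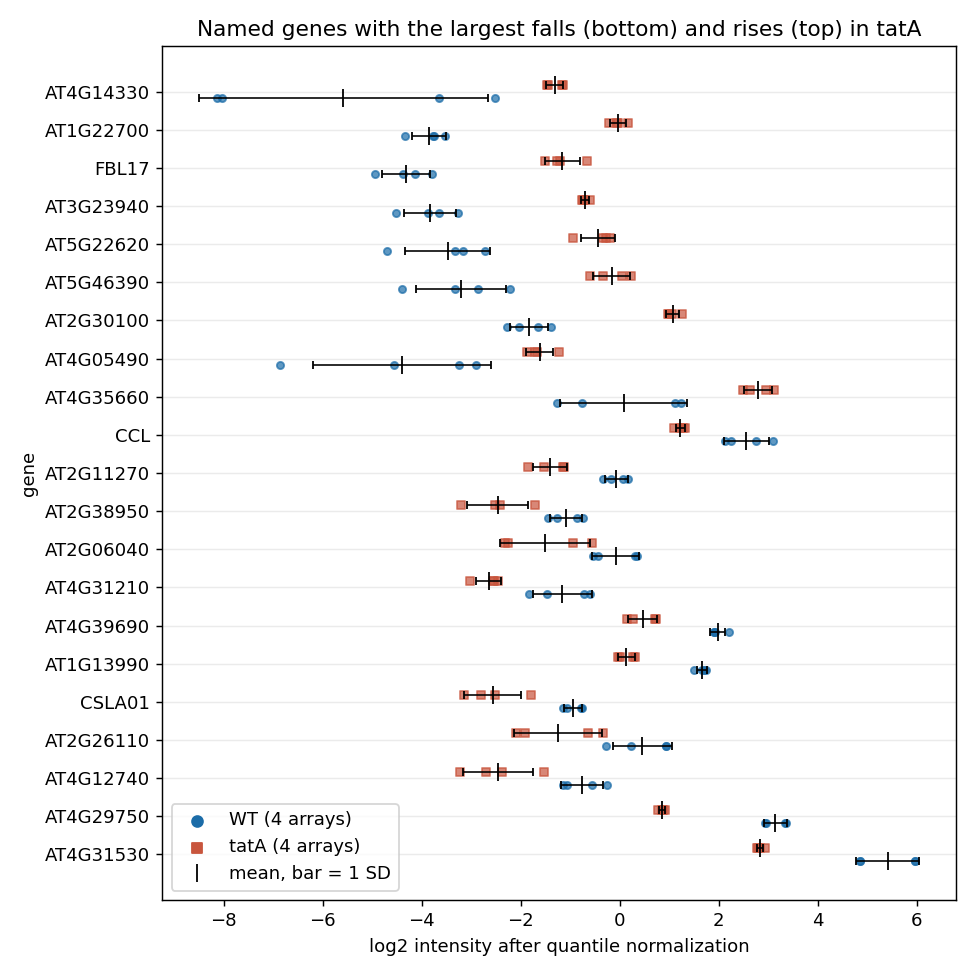
Log2 intensity after quantile normalization of the named genes with the largest falls (12, bottom) and rises (9, top) in tatA, for genes with no array at 0. Each point is 1 array (WT circles, tatA squares), and ticks with bars give the mean and 1 SD of 4 arrays. In each gene shown the 4 tatA arrays lie on 1 side of the 4 WT arrays. AT1G22700 and AT4G29750 show narrow groups, and AT4G14330 shows a wide spread among WT arrays.

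Among spots without a gene name, the largest changes joined a group at or near 0 with a group above it. Spot 2580 was at 0 on 3 WT arrays and had a mean of 0.463 ± 0.0989 in tatA (SD, n = 4 arrays; limma adjusted p = 0.000227). Spot 2674 was at 0 on all 4 WT arrays, with a tatA mean of 0.194 ± 0.0430 (adjusted p = 0.000879). In the other direction, spot 3102 had a WT mean of 0.738 ± 0.147 and was at 0 on all 4 tatA arrays (adjusted p = 9.5e-05). Spot 3530, with a WT mean of 0.248 ± 0.124, was also at 0 on all 4 tatA arrays (adjusted p = 0.000958). Spot 3530 carries the number after that of PSBW, a bright spot that rose in tatA. Spot 3102 carries a number within 2 of spot 3100, which was at the upper limit of the scale (100) in tatA.

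Of the 22 gene lists on plastid functions and other cell types, fixed before the data were examined, few members could be measured. Of 375 genes in the lists, 24 were named on the array and 20 were tested, the other 4 being at 0 on more than 4 of the 8 arrays, and 12 lists had no tested member. Photosystem II was represented by 3 genes. PSBW, a small subunit of the reaction centre complex, rose from 13.3 ± 0.346 to 26.5 ± 2.27 (SD, n = 4 arrays), a log2 change of 0.87 (SE 0.07, limma adjusted p = 6.04e-05), and of 1.34 with median centring and 1.38 with 75th percentile scaling. PSBW ranked 11 from the top on all 4 tatA arrays, so that quantile normalization gave it 1 value there, and the SE leaves out their spread in intensity. PSB27, an assembly factor in the lumen, had a log2 value of -0.59 (adjusted p = 0.0605) and PSBY one of 0.51 (adjusted p = 0.149). With the replicate number as a fixed block both passed (adjusted p = 0.00193 and 0.0359), but with the replicate pairs as a random block neither did (0.237 and 0.274). With values centred on neighbouring spot numbers PSBY had a log2 value of 1.04 and passed, alone (adjusted p = 0.00141) and with the pairs as a random block (0.00711). Adjusted over the list alone, PSBW and PSB27, which went opposite ways, passed. The light-harvesting protein gene LHB1B2 had a log2 value of 0.39 (adjusted p = 0.0624, 0.031 with the replicate number as a fixed block, and 0.297 with the replicate pairs as a random block). It passed when adjusted over the list alone, being its only member tested.

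Of the lumenal proteins with a known or predicted twin-arginine signal, 5 were named on the array, of which FKBP19 and TL15 were left out for their zeros, 3 were tested, and 1 rose. AT5G35100, a cyclophilin-type peptidyl-prolyl isomerase, rose by 1.23 on the log2 scale (SE 0.20, limma adjusted p = 0.00221), from 0.437 ± 0.0839 to 0.782 ± 0.0518 (SD, n = 4 arrays), and was also the 1 gene to pass when adjusted over the list alone. PSAN, the lumenal subunit N of photosystem I and the only member tested of the photosystem I list, had a log2 value of 0.16 (adjusted p = 0.227), and of -0.16 on the deposited scale. AT1G76450, a PsbP-domain protein, had a WT mean of 0.0405 ± 0.0134 and was at 0 on all 4 tatA arrays, and did not pass (adjusted p = 0.122). After normalization its 4 zeros had log2 values from -11.86 to -9.40, a spread made by processing. Its log2 value was -0.24 with the offset and -7.65 on the deposited scale. Without the intensity trend it passed (limma adjusted p = 0.00244), so neither call is firm. The spot number of AT1G76450 is next to that of AT4G35660, which rose. The median log2 value of this list was 0.16 and its mean -1.01, which AT1G76450 at 0 sets. Of the components of other routes into the thylakoid, only SECE1, the E subunit of the thylakoid Sec translocase, was tested. It fell from 1.05 ± 0.293 to 0.507 ± 0.0220 (SD, n = 4 arrays), a log2 change of -0.64 (SE 0.15, adjusted p = 0.0135, and passing adjusted over the list alone, where it is the only member), and of -1.01 on the deposited scale. The change was -0.32 in replicates 1-2 and -0.96 in replicates 3-4. SECE1 passed with the replicate pairs as a random block (limma adjusted p = 0.0407). It did not pass with each pair averaged (0.224), nor with the pair number as a block too (0.216).

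Of 2 chlorophyll synthesis genes, AT1G74470, the geranylgeranyl reductase that makes the phytyl chain of chlorophyll and tocopherol, rose by 0.50 (SE 0.09, limma adjusted p = 0.00413). This call was lost on the deposited scale (log2 value 0.12, adjusted p = 0.452). CHLM, the magnesium protoporphyrin methyltransferase, had a value of -0.003 (adjusted p = 0.997). The only carotenoid gene tested, Z-ISO, had a value of -0.37 (adjusted p = 0.274). The Calvin cycle genes SBPASE and PRK had values of 0.52 and 0.14 (adjusted p = 0.509 and 0.754), the latter -0.19 on the deposited scale. Adjusted over the list alone, AT1G74470 passed, and Z-ISO, SBPASE and PRK did not.

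Among 4 plastid ribosomal protein genes, AT4G01310 (ribosomal protein L5) rose 2.01-fold (limma adjusted p = 0.0398), and AT3G54210, AT3G13120 and AT1G64510 did not pass. AT4G01310 did not pass with the replicate number as a fixed block (adjusted p = 0.062), with the replicate pairs as a random block (0.110), on the deposited scale (0.175), or in 6 of 8 fits that left out 1 array (0.0271 to 0.0867). Among 3 antioxidant and thioredoxin genes, AT3G52960, a chloroplast peroxiredoxin of type II, rose by 1.85 (SE 0.62, adjusted p = 0.0476). It did not pass with the replicate pairs as a random block (adjusted p = 0.114), on the deposited scale (0.0515), or in 6 of 8 fits that left out 1 array (0.029 to 0.112). The size of this rise is poorly fixed, at 1.04 in replicates 1-2, 2.66 in replicates 3-4 and 1.32 with the offset. Leaving out 1 array moved it between 1.24 and 2.22. AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, had a log2 value of -0.47 (adjusted p = 0.081), and NTRC, a thioredoxin reductase of the chloroplast, one of -0.30 (adjusted p = 0.399). Adjusted over the list alone, AT4G01310 passed among the ribosomal genes, and AT3G52960 and AT2G04700, which went opposite ways, passed in their list.

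The 4 lists with at least 3 tested members were set against all other genes with limma's camera, and 0 shifted at an adjusted p under 0.05 or at an unadjusted p under 0.05. These were photosystem II and the lumenal twin-arginine list (adjusted p = 0.675 for both), plastid ribosomal proteins (0.764) and antioxidant enzymes (0.930). With an estimated correlation between genes, the lowest adjusted p was 0.740. Limma's fry, which asks whether the genes of a list move on balance one way without comparing them with others, called photosystem II upward (adjusted p = 0.00767). Of the 3 genes of that list only PSBW, whose SE leaves out spread in intensity, had passed over all rows, and PSB27 had a negative value. Fry took the arrays of a group as independent and was not run with the replicate pairs as a block. The antioxidant list had a median of -0.30, a mean of 0.36 and a downward direction in camera.

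No member was tested of the TAT subunits, lumenal proteins of the Sec route, photoprotective proteins, electron transport and ATP synthase, plastid transcription, plastid chaperones and proteases, and envelope import. Nor was any of starch metabolism, photorespiration, jasmonate and cold stress proteins, non-green plastids, or epidermis and vascular tissue.

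The 8 arrays separated by group along the first principal component (35.5% of the variance). The second (23.5%) separated replicates 1 and 2 from replicates 3 and 4 in both groups. Pearson's correlation across genes, which are not independent replicates, was 0.807 to 0.884 between the arrays of such a pair. It was 0.720 to 0.754 between the other arrays of 1 group. Between WT and tatA arrays that were both from replicates 1-2 or both from replicates 3-4, it was 0.635 to 0.717. The median per-gene SD on the log2 scale was 0.293 over the 4 WT arrays and 0.314 over the 4 tatA arrays, but 0.118 to 0.182 within pairs. Nothing in the labels says that the arrays came from separate plants, so that p-values measure only the spread between these arrays, which may be technical.

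**Figure D3:**
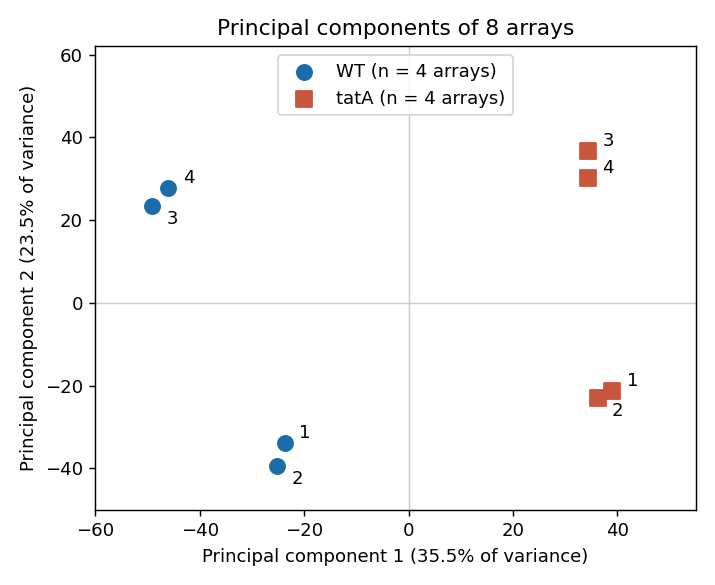
First and second principal component of the 8 arrays, with the share of variance on each axis; points are arrays (WT circles, tatA squares) and numbers are replicates. WT and tatA lie on opposite sides of 0 on the first component, and replicates 1 and 2 of both groups lie below 0 on the second, with replicates 3 and 4 above.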

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

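The count of other splits and the tests of the pairs, of spot numbers and of zeros were all written down only after the results were seen; the rule for a sample far from the others of its group was set beforehand.

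In 6 of 96 groups of 4 arrays checked, 1 array lay far from the other 3. For 4 independent values with normal errors, chance gives about 1 in 20. These arrays fall into pairs and many of the genes were chosen by their values, so that share is not a measure for them. The number given is the gap to the nearest array as a share of the range, both on normalized log2 values. For AT4G31930 it was WT replicate 1 (gap 1; log2 value -4.38 against -11.86, the others being at an intensity of 0), and for spot 2580 WT replicate 4 (gap 1; intensity 0.0160 against 0 on the others). Where the other 3 arrays are at 0 they share the same log2 value, so any signal on the remaining array gives a gap of 1. The gaps of AT4G31930 and spot 2580 were thus set by the treatment of zeros and cannot be weighed against chance. For AT2G22050 it was tatA replicate 1 (gap 0.856; log2 value -2.14 against -4.01 to -3.74). For AT4G39690 it was WT replicate 3 (gap 0.911; 2.21 against 1.89 to 1.92). For AT4G31210 it was tatA replicate 4 (gap 0.832; -3.03 against -2.56 to -2.47), and for AT4G01310 tatA replicate 3 (gap 0.926; -1.46 against -1.08 to -1.05).

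The first pattern is the pairing of arrays within groups, on which the number of calls depends: all 8 arrays correlated best with their mate in replicates 1-2 or 3-4, which only restates the pattern, so repeat hybridizations of 1 RNA sample and preparation in common stay open. The tables argue against a batch shared by both groups as the whole source of the difference between replicates 1-2 and 3-4: across genes that difference correlated between WT and tatA at a Spearman's rho of 0.136, where the agreement between repeats (0.639 in WT, 0.436 in tatA) would allow 0.688. Of 35 splits only 1, the real one, gave as many as 1046 calls (highest other 22, which split replicates 1-2 from 3-4), but this excludes chance only for independent arrays: 3 splits keep the pairs whole (1 as large, highest other 22) and 8 part all 4 numbered pairs (highest other 0), too few for a share under 0.05. With pairs averaged, so that groups are set against the spread between pairs, 57 genes passed at an adjusted p under 0.05 (limma). With the pair number as a block too, which removes a shift common to both groups, 208 passed, 204 of them among the 1046. Among both were AT1G22700 (3.64 in replicates 1-2 and 3.99 in replicates 3-4), AT2G30100 (2.64 and 3.17) and AT4G29750 (-2.13 and -2.45). For calls that passed in neither, a difference between genotypes and differences between the pairs of each genotype stay open, and for all calls a batch that coincides with genotype does.

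The second pattern is that fold changes were alike in spots with neighbouring numbers (Spearman's rho 0.184 between adjacent numbers, 0.215 at 6 apart and 0.209 at 288 apart; the largest of 1000 shuffles gave 0.0775, 0.0619 and 0.0631). The difference between replicates 3-4 and 1-2 of WT, which holds no genotype contrast, showed it more strongly between adjacent numbers (0.364), which is consistent with an effect of position on the array. Related genes with successive numbers were argued against as the only source, since the correlation at 288 apart (0.209) exceeded all values at 60 to 240 apart (-0.149 to 0.0746), 288 being the far distance at which the WT difference correlated most. That test bears only on a likeness that falls with distance, and cannot exclude related genes as part of the likeness at adjacent numbers. The mean level of spots was also alike at 288 apart (Spearman's rho 0.154) and at 6 apart (0.116). After centring on neighbouring numbers the correlation at 6 apart was 0.0475 and 987 genes passed, 726 of them among the 1046. Apart from related genes with successive numbers, no biological explanation was tested, and the layout of the array was not used here.

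The third pattern concerns spots that vanish in tatA. Of 25 spots at 0 on at least 3 tatA arrays and on no WT array, 36% (9) lay within 2 numbers of 1 of the 20 brightest spots, against 1.70% of all spots (Fisher's exact test, two-sided, p = 1.01e-10). This is consistent with a local background raised by bright neighbours; 3 spots showed the reverse pattern and 0 of them lay beside a bright spot. Spots 3102 and 3530 belong to the 9, which lay beside 7 distinct bright spots, 4 of them brighter in tatA (such as PSBW at 13.3 in WT and 26.5 in tatA), 1 dimmer (spot 3499 at 24.9 and 20.7) and 2 at the limit in both groups; of all 20 bright spots 10 were brighter, 7 dimmer and 3 at the limit, so why the loss is in tatA stays open. Every tatA array also had more spots at 0, and a lower median intensity, than every WT array. An excess of zeros in tatA was thus general to its arrays and not limited to spots beside bright ones. Whether this accounts for the 25 spots against 3 was not tested. A loss of the transcripts in the tatA line stays open and was not tested.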

How the results depend on the processing

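The settings with replicate pairs, with any 0 left out and with local centring were chosen after seeing the data; the others were planned. The count of genes that passed, 1046, stayed between 746 (without the dimmest 50% of genes, where fewer were tested) and 1444 (replicates 3-4 only) under all settings but 4. With the replicate pairs as a random block it was 537, all of them among the 1046, and with local centring as well 625 (517 shared). With pairs averaged it was 57, and 208 with the pair number as a block too, where fewer values enter. Leaving out 1 array gave 784 (without WT replicate 3) to 951. The replicate number gave 1027 as a fixed and 1176 as a random block. The deposited scale gave 1390, 22.3% of them higher against 47.7%. With the replicate number as a fixed block, no call of a gene or spot named in the text changed but those of AT4G01310, PSB27, PSBY and LHB1B2, and of NdhS, AT1G62150, AT1G79220 and AT2G46910 under the other observations. Of the list tests, 0 lists passed under every setting of camera, and fry called 1. Camera was not run with robust variance or random blocks, and fry was run with the main setting only. The alternatives for TATA were not run. The median correlation between arrays of a group, 0.748, was 0.736 on the deposited scale and 0.897 without the dimmest 50% of genes; what part background has in the lower agreement of dim genes was not tested.

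Of 47 named genes and spots followed over all settings that kept them, 34 had passed. None of these reversed, and 21 kept their call under all settings but the averaged pairs. With pairs averaged, AT1G22700, AT3G23940, AT2G30100, AT4G31530, AT4G29750, AT1G13990 and spot 3102 passed. AT2G22050 was also lost with every other scaling, robust variance and array weights (adjusted p = 0.088 with median centring; 0.0118 to 0.230 over its alternatives), and AT2G06040 without the trend (0.0524; 0.000607 to 0.226). AT3G52960 was also lost without the trend and with array weights (0.0697 and 0.0815; 0.00533 to 0.229). Of genes that had not passed, PSB27, AT2G04700, AT3G54210, NTRC and Z-ISO passed as lower on the deposited scale, LHB1B2 as higher with median or 75th percentile scaling, AT1G76450 as lower without the trend, and PSBY as higher with local centring. PSB27 and LHB1B2 also passed without the dimmest 50% of genes and with the replicate number as a random block, and PSB27 with array weights. PSB27 and PSBY passed with the pair number as a fixed block on all arrays, but not where the pairs were averaged as well. PSB27, LHB1B2 and AT2G04700 passed without 1 of the arrays (lowest adjusted p = 0.0303, 0.00353 and 0.0443). In replicates 1-2 alone, AT4G12740, AT4G31210, AT4G31930, AT2G22050, AT2G38950 and SECE1 did not pass, and PSAN and PSB27 did. In replicates 3-4 alone AT4G01310 did not pass, and LHB1B2, Z-ISO, AT3G54210, AT3G13120 and NTRC did. The 8 of the 47 that changed sign had not passed, and the cause was not tested. On the deposited scale, log2 values were -0.16 for PSAN, -0.19 for PRK and -0.10 for AT3G13120. CHLM was at 0.029 with 75th percentile scaling and 0.011 with the offset. In replicates 1-2 only, CHLM was at 0.45, Z-ISO at 0.0059, AT3G54210 at 0.0070, AT3G13120 at -0.63 and NTRC at 0.020. In replicates 3-4 only, PRK was at -0.16. With local centring, alone or with the pairs as a random block, CHLM was at 0.50, Z-ISO at 0.13, AT3G54210 at 0.18, AT3G13120 at -0.012 and NTRC at 0.18. Z-ISO, AT3G54210 and NTRC carry nearby spot numbers (1756, 1739 and 1759), so their like values need not be separate observations. Leaving out 1 array, CHLM ran from -0.20 to 0.22, PRK from -0.099 to 0.39, SBPASE from -0.044 to 1.07 and AT3G13120 from -9.8e-05 to 0.91.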

Other observations

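The gene lists in this part were written after the annotation and some values had been seen, so their counts are descriptions only. Over all 3261 rows tested 32.1% passed, and 203 of the 646 with a gene name did. Some members of any list would therefore pass, and the counts do not set a family apart. Among 16 tested genes for pentatricopeptide repeat proteins, which process organelle RNA, 3 rose, 2 fell and 11 did not pass. AT2G46050 rose by 1.64 on the log2 scale (limma adjusted p = 0.000273), AT1G31790 by 1.64 (0.018) and AT5G39980 by 0.91 (0.00274). AT4G14050 changed by -0.78 (adjusted p = 0.00335) and OTP70, needed for splicing of a plastid transcript, by -0.46 (0.0203). AT1G31790 and OTP70 did not pass with the replicate pairs as a random block (adjusted p = 0.0635 and 0.0986). Of 6 genes for the chloroplast NDH complex and factors its activity needs, CRR41 rose by 1.52 (adjusted p = 0.00868, and 0.0658 with the pairs as a random block), and NdhS, NdhN, CRR21, PIFI and OTP85 did not pass. NdhS passed with the replicate number as a fixed block (adjusted p = 0.0459), at a log2 value of 0.23, and not with the pairs as a random block (0.408).

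Of 5 genes for fibrillins, proteins of plastoglobules and thylakoids, AT5G09820 (FBN5) rose by 1.98 (limma adjusted p = 0.000902), from an intensity of 0.204 ± 0.0469 to 0.613 ± 0.0496 (SD, n = 4 arrays). AT2G46910 changed by -0.52 (adjusted p = 0.0471, 0.062 with the replicate number as a fixed block and 0.162 with the pairs as a random block), and 3 did not pass. Among 6 genes of the organelle mTERF family, AT1G61990 rose by 0.72 (adjusted p = 0.0153) and AT1G79220 by 0.69 (0.0343), while 4 did not pass; with the pairs as a random block neither rise passed (0.0683 and 0.081). With the replicate number as a fixed block AT1G79220 did not pass (adjusted p = 0.0675), and AT1G62150, at a log2 value of -0.61, did (0.0322; 0.181 with the pairs as a random block). None of these 4 lists shifted against all other genes in camera (lowest adjusted p = 0.784, and 0.822 with an estimated correlation; 0 at an unadjusted p under 0.05), nor on balance one way in fry (lowest adjusted p = 0.237).

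The 2 pairs of replicates gave different numbers of calls. Replicates 1-2 alone gave 932 and replicates 3-4 alone 1444. Of the genes that passed in both, 609 had the same sign and 23 the opposite sign.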
